A study of Citrus maxima and Citrus sinensis with 12 samples.

How the data were processed

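Small RNA was measured in 12 root-tip libraries of C. grandis and C. sinensis seedlings that were 11 weeks old at the start of sand culture and were then irrigated with 10 or 400 µM H3BO3 for 15 weeks. Per the labels, libraries were made with the TruSeq small RNA kit from mixed total RNA of 5 replicates and sequenced single-end on a HiSeq 2500. Trimming, aligner, miRNA caller and genome build were not given in the sources used here, and DESeq, without a version, is the only tool that the processing notes name. The deposited expression table holds counts, whole numbers per miRNA locus made by the authors without normalisation. Of its entries 73 share their mature sequence with another entry, so that reads of a shared sequence were counted at each of its loci. The deposited table of boron-responsive miRNAs holds the authors' log2 fold changes with a p-value and a false discovery rate for each entry; 1 log2 cell (mir7496) is a spreadsheet error, and in the first 3 entries the columns of name and identifier are swapped. The deposited table of identified miRNAs gives a score of the hairpin prediction, coordinates and the mature sequence, with windows of 250 nt for 170 entries. The deposited target table gives predicted genes and their annotation. The table of boron-responsive miRNAs was used only for names and for the comparison with the fit, and the target table only for the predicted targets. The table of identified miRNAs gave names, positions and the mature sequences, on which the entries per sequence, the lengths and the edit distances rest.

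Groups were species by boron level, 4 groups of 3. Counts were tested with edgeR 4.0.16 (R 4.3.3), using trimmed-mean scaling, the filterByExpr filter at its count minimum of 10 (170 entries kept, with miR171 of ccl-miR171 and miR9560 left out) and a quasi-likelihood fit with 1 mean per group over all 12 libraries. The 5 contrasts were the boron effect in each species, the difference of these effects, and the species difference at each level, each two-sided with Benjamini-Hochberg adjusted p under 0.05. Standard errors are approximate, taken as the absolute log2 fold change over the root of the F statistic. The biological coefficient of variation was 28.1% over all libraries, 34.9% in C. grandis alone and 19.4% in C. sinensis alone. CPM values use the trimmed-mean library sizes, with a prior count of 2 on the log scale. Replicate libraries had a Pearson correlation of log2 CPM of 0.968 to 0.995 and differed by more than counting error in every pair. A ratio against 1 to 3 counts carries a 95% exact counting interval, and a group at 0 counts was set to 3 counts over the group.

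Of 12 lists of miRNA families fixed by family number, 11 had at least 3 tested members and were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation and fry beside it, adjusted over the lists. Family lists overlap, since miR319 stands in 3 of them. Named miRNAs were all miR319 and miR171 members in the boron comparisons, called miRNAs with non-overlapping groups up to 10 per direction, called list members up to 3 per list, the 5 with the smallest p where fewer than 5 were called, the 5 largest per direction in the species comparisons and the 5 most abundant overall; other miRNAs named in the text (list members, conserved families and the copper-related pair) were chosen after their values were seen. Groups, contrasts, tests, lists, this naming rule and most alternatives were fixed before the data were examined. Correlations across miRNAs used 100000 permutations, and library quantities used exact permutation tests.

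Whether replicate numbers pair libraries across boron levels was checked on deviations from group means. In C. sinensis the correlations of equal numbers were 0.40, 0.24 and 0.22 and each library matched its own number best, whereas in C. grandis they were −0.12, −0.23 and 0.20; the labels do not say that numbers are shared, so the unpaired fit was kept and the replicate block was an alternative. The alternatives were median-of-ratios and total-count scaling, DESeq2 1.42.0 without independent filtering, no filter, a mean CPM of at least 10, identical loci merged, only the 6 libraries of a species or level, a log2 change of at least 1, and each library left out in turn. Alternatives for normalised values were not used here, because the table holds counts.

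The tests were tested on simulated data with 20 sets and 20 changed of 170 entries in each. At a 2-fold change 45.5% of changed entries were found in each boron comparison, 18% in the difference of effects and 44% and 48.5% in the species comparisons, and at a 4-fold change 94%, 90.5%, 78%, 94% and 96%. False calls were 2.16% to 8.13% of calls. Before the changes were added, each entry was drawn with the same level and the same spread in all 4 groups, pooled over both species. In the data the biological coefficient of variation was 34.9% in C. grandis alone and 19.4% in C. sinensis alone. The shares of found entries and of false calls may therefore not hold in either species on its own. The list test was simulated for the boron effect in C. grandis only. There 0 lists were called in 20 sets without change, and a list shifted 2-fold was found in 20 of 20. The simulated entries were drawn independently of each other. In the data the estimated correlation within a list reached 0.74 (developmental timing) and 0.81 (citrus lineage), so the simulation does not bound false list calls there.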

Results

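Small RNA was sequenced from the root tips of 2 citrus species, C. grandis (pummelo, recorded as Citrus maxima) and C. sinensis (sweet orange), after 15 weeks of irrigation with 10 µM (control) or 400 µM (toxic) H3BO3, the boric acid that supplied boron. The 12 libraries formed 4 groups of 3, and per the labels each library was made from the mixed RNA of 5 replicates. Whether libraries of a group share plants was not given, so it stays open whether their spread, on which every SD and p-value rests, is that of independent biological replicates. The count table held 1 entry per miRNA locus, 170 of them abundant enough to be tested, with 126 distinct mature sequences of 19 to 25 nt over all entries. Library totals ran from 479090 to 1062488 counts, or from 282149 to 577150 when each sequence was counted once. An unnamed 20-nt sequence (scaffold_1_3278) was among the most abundant entries in every group, at 101418 to 111938 mean CPM (counts scaled to the library size). miR159a, a regulator of MYB transcription factors, was at 65390 to 97423 CPM, miR165a-3p, which targets class III HD-ZIP factors of root patterning, at 55604 to 75188 CPM, and miR3951 in the 2 C. sinensis groups at 119324 and 124836 CPM. Total counts, the share of the most abundant entry and the shares of 21-, 22- and 24-nt entries were compared between boron levels in 10 two-sided exact permutation tests, which cannot go below p = 0.1 with 3 against 3 libraries (lowest p = 0.2, adjusted p = 1). Intervals of count ratios and count limits cover counting error only, and intervals of log2 changes come from the edgeR fit and include the spread between libraries.

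The first comparison asked how long-term excess boron altered the miRNAs of C. grandis root tips. Of 170 miRNA entries tested, 2 fell at 400 µM and 0 rose. miR3951, a family described in citrus, fell from 1048 ± 1184 to 43.0 ± 23.9 CPM (SD, n = 3), a log2 change of −4.63 (SE 0.74, adjusted p = 0.00555). The 24-nt ci-miRN17 fell from 118 ± 98.9 to 17.3 ± 8.25 CPM (SD, n = 3), a log2 change of −2.78 (SE 0.54, adjusted p = 0.0167). In both, all 3 libraries at 400 µM lay below all 3 at 10 µM. Replicate 3 at 10 µM held 1935 miR3951 counts against 318 and 334 in the other libraries of its group, and without it the log2 changes were −3.37 and −2.15, both still past the threshold; without 400 µM replicate 2 miR3951 was at −5.26. The miR3951 locus was on scaffold 1, plus strand, within a hairpin window from 20960909 to 20961158, with the mature sequence uuucucuuaucguuaucugug, and ci-miRN17 (guacuguagcugugagggggacgu) was on scaffold 3, minus strand, from 50071563 to 50071812. The genome build was not given in the sources used here, and the annotation of these positions was not analysed here.

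miR319, which acts on TCP growth regulators and is named in the series title, did not pass the test in C. grandis at any of its 7 loci. Its abundant 20-nt form (scaffold_3_9747) averaged 2007 ± 646 CPM at 10 µM and 3366 ± 1277 CPM at 400 µM (SD, n = 3), a log2 difference of +0.75 (SE 0.28, adjusted p = 0.156). The 7 miR319 loci ranged from +0.25 to +1.11, with miR319-5p at +1.11 (SE 0.61, adjusted p = 0.339); without 10 µM replicate 3 miR319-5p was at +0.61, and without 400 µM replicate 3 the 20-nt form was at +0.41. The 5 tested miR171 loci, of a family that acts on GRAS-domain factors of the root meristem, ranged from +0.13 to +0.90. The 5 loci hold 2 sequences. miR171b.1 to miR171b.4 had similar counts in each library, from 3 to 57, so they are not 4 independent measurements. Without 400 µM replicate 3 the 4 higher ones, miR171b.1 to miR171b.4, were at only +0.11 to +0.26, and the lowest, ath-miR171b-3p, turned to −0.14 under total-count scaling, with no filter and with a filter on mean CPM, and was below 0 without 400 µM replicate 1 or 3 or 10 µM replicate 2 or 3 (lowest −0.29). Without 400 µM replicate 2 the 3 ath-miR319a loci and gma-miR319g were below 0, and without 10 µM replicate 2 the 3 ath-miR319a loci were (lowest −0.14). Next after the 2 called miRNAs stood miR3627.2 at +1.05 (SE 0.28) and miR3954 at −0.98 (SE 0.26, 2 loci with identical counts), each at adjusted p = 0.0788. miR472, a trigger of phased small RNAs from disease-resistance transcripts, was at +0.68, and miR167h, of a family that acts on auxin response factors, at +0.64. Both had the same adjusted p. Without adjustment 31 entries had p under 0.05, 22 higher and 9 lower at 400 µM, and 23 entries (13.5%) had non-overlapping groups, where chance gives 10%. DESeq2 called 5 entries (34 at unadjusted p under 0.05), adding both miR3954 loci (−1.05, adjusted p = 0.00513) and miR3627.2 (+0.98, adjusted p = 0.0427). Median-of-ratios and total-count scaling each called 4 entries, and total-count scaling shifted the median log2 change of all entries by −0.24. The count was 0 without 400 µM replicate 1 (miR3951 adjusted p = 0.0645, ci-miRN17 0.0944), 8 without 400 µM replicate 2, 4 without 400 µM replicate 3, 0 in a fit of the 6 C. grandis libraries alone (0.0572 and 0.193) and 1 in that fit with the replicate block (miR3951, 0.0279); over all alternatives run the adjusted p of miR3951 ran from 3.94e-08 to 0.0645 and that of ci-miRN17 from 3.99e-07 to 0.193.

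**Figure D1:**
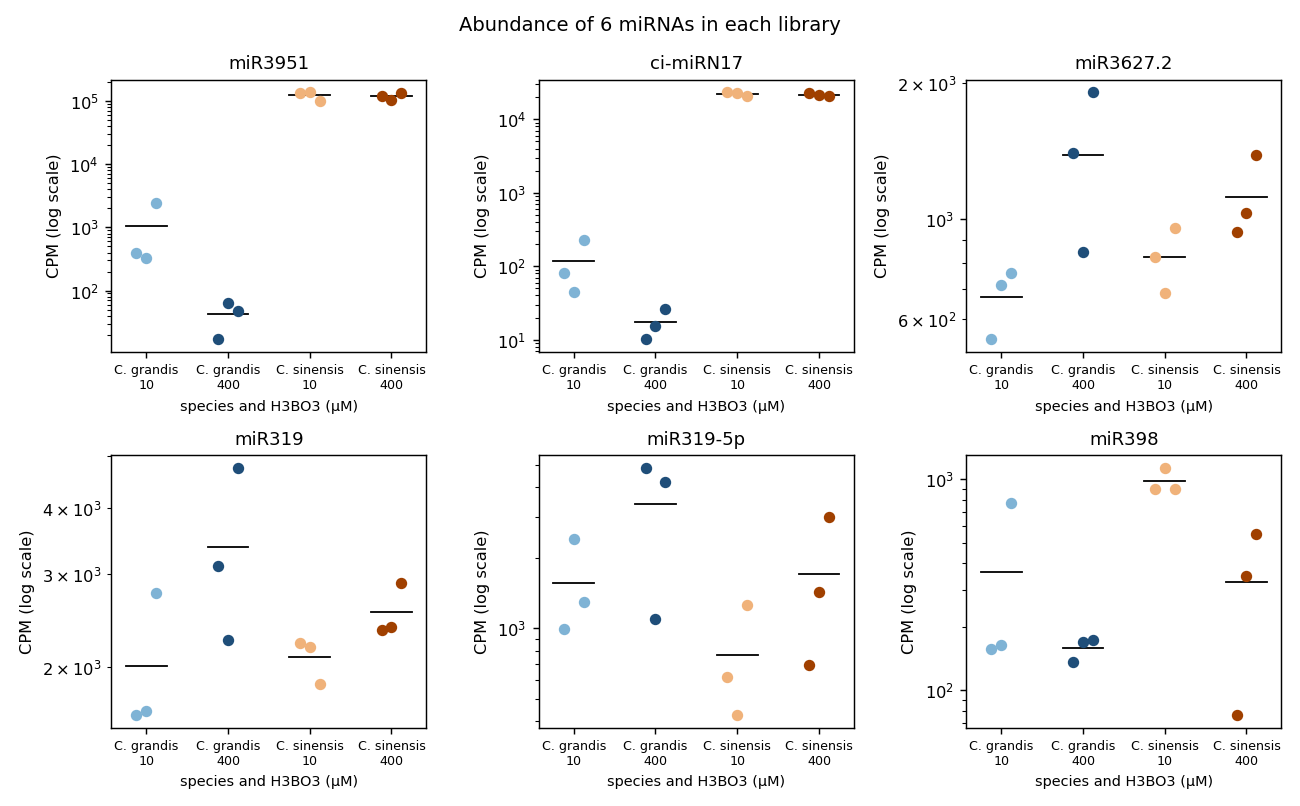
Normalised abundance (CPM, log axis) of 6 miRNAs in the 12 libraries, by species and H3BO3 level; each point is a library and each bar the mean of 3. For miR3951 and ci-miRN17 the C. grandis libraries at 400 µM lie below those at 10 µM, and both lie far below C. sinensis.

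Among the miRNA families grouped by function, those of developmental timing (miR156, miR157 and miR172, which act on SBP and AP2 factors) shifted upwards in C. grandis relative to all other miRNAs. All 6 members had higher values, with miR157 at +0.90 and miR156 at +0.63, 0 members passed alone, and the list had adjusted p = 0.0193 (adjusted p = 0.462 with an estimated correlation). Growth and stress regulators (miR159, miR319, miR394 and miR396) also shifted upwards, with 17 of 19 members higher, 0 passing alone and adjusted p = 0.00722 (adjusted p = 0.462 with an estimated correlation). In this list miR159a was at +0.58, and miR396g-5p, of a family that acts on growth-regulating factors, at −0.67. The 63 conserved land-plant members had 47 higher values, 0 passing alone and adjusted p = 0.000285 (adjusted p = 0.328 with an estimated correlation). Citrus-lineage families (miR3951 and 2 miR3954 loci) shifted downwards, with 3 of 3 lower and adjusted p = 3.52e-05 (adjusted p = 0.181 with an estimated correlation). Of these 3, 1 passed over all miRNAs and 3 passed when adjusted over the list alone. The 34 entries with no family name shifted downwards, with 21 lower values and adjusted p = 0.0415 (adjusted p = 0.328 with an estimated correlation), and 1 passed both over all miRNAs and when adjusted over the list alone.

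Root development families (miR160, miR164, miR165, miR166, miR171, miR319 and miR390) did not pass in C. grandis, with 23 of 31 members higher and adjusted p = 0.166. Auxin signalling had adjusted p = 0.260, and its mixed-direction fry test had adjusted p = 0.0215. Of its 12 members 4, all miR167 loci between +0.62 and +0.64, passed when adjusted over the list alone, against 0 over all miRNAs. These 4 loci hold 3 sequences, and miR167a and miR167b had identical counts, so they are not 4 independent measurements. Nutrient supply had adjusted p = 0.237, with 3 miR395a loci of 1 sequence, regulators of sulfate assimilation, at +1.07. The list fixed as triggers of defence-gene silencing had adjusted p = 0.435. Adjusted over the list alone, 3 of its 5 members passed, miR472 higher and 2 miR3954 loci lower, against 0 over all miRNAs. The 2 miR3954 loci share 1 sequence. Its 1 predicted target is annotated as weak chloroplast movement under blue light and not as a resistance gene, so its fall is not shown to be one of a defence trigger. Regulators of the small RNA machinery (adjusted p = 0.971) had a median of −0.04 and a mean of +0.03, and the other stress families (adjusted p = 0.971) had a positive median (+0.09) and mean (+0.11) and a negative direction in camera. In the root, nutrient, small RNA and other stress lists 0 members passed over all miRNAs and 0 when adjusted over the list alone. Copper and laccase families had 2 members, too few for the test, miR398 at −1.20 and miR397-3p at −0.93. Both values rest largely on 10 µM replicate 3. At 10 µM miR398 had 155.9, 163.95 and 775.0 CPM in replicates 1, 2 and 3, against 135.6, 169.6 and 172.5 CPM at 400 µM. For miR397-3p these were 38.7, 69.6 and 249.6 CPM against 118.8, 43.6 and 21.9 CPM. In both, 10 µM replicates 1 and 2 lay within the range of the 400 µM libraries. None of the 5 list calls held with an estimated correlation, and fry, which does not compare a list with other miRNAs, called 1 (citrus lineage, adjusted p = 0.0234). The count of lists was 3 without 400 µM replicate 1, 1 without 10 µM replicate 1 and 3 without 10 µM replicate 2; it was 3 with identical loci merged or with miR3951 and ci-miRN17 left out, and 2 with 1 entry per sequence, and in these last 3 settings the citrus-lineage list had too few members to be tested.

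**Figure D2:**
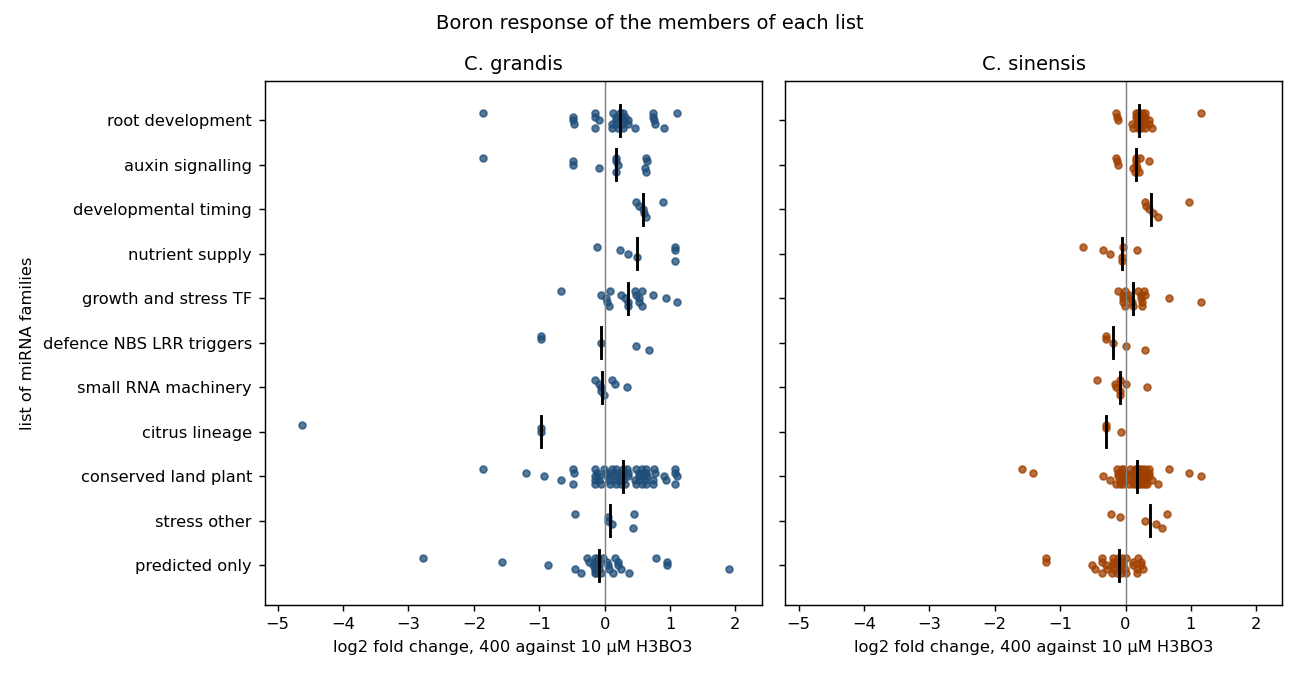
Log2 fold change at 400 against 10 µM H3BO3 of each member of the 11 tested lists, in C. grandis (left) and C. sinensis (right); points are miRNA loci and black bars list medians. All 6 developmental timing members lie above 0 in both species.

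The same question in C. sinensis, the species with far more miR3951, gave 0 called miRNAs in edgeR and 0 in DESeq2, with 3 and 4 entries at unadjusted p under 0.05. Among these 3, miR398, which acts on copper-containing superoxide dismutase transcripts, averaged 977 ± 135 CPM at 10 µM and 325 ± 238 CPM at 400 µM (SD, n = 3), and was lower in 3 of 3 treated libraries than in all controls. Its log2 difference was −1.58 (SE 0.65, adjusted p = 0.887). miR477 was at +0.63 (SE 0.25) and mir7496 at −0.50 (SE 0.23), and miR156k at +0.98 and csi-miR477b at +0.56 came next, all at adjusted p = 0.887. miR319 loci ranged from +0.19 to +1.15, with the 20-nt form at +0.28 (SE 0.27) and miR319-5p at +1.15 (SE 0.61, adjusted p = 0.887), and miR171 loci from +0.17 to +0.40, of which miR171b.2 and miR171b.3 were below 0 without 400 µM replicate 3 or 10 µM replicate 1 (lowest −0.15). Single libraries moved these values: without 400 µM replicate 3 miR398 was at −2.15, miR156k at +0.32 and miR319-5p at +0.50, without 400 µM replicate 1 miR398 was at −1.21, and without 10 µM replicate 3 miR156k was at +1.38 and miR319-5p at +1.72. miR3951 (−0.07, 95% interval −1.37 to 1.23) and ci-miRN17 (−0.03, −0.93 to 0.86) stayed near 0. Non-overlapping groups were found for 17 entries (10.0%, where chance gives 10%). The count was 0 under all alternatives but 1, a fit of the 6 C. sinensis libraries with the replicate block. That fit called miR397-3p, the 3p arm of a family that acts on laccases, at −1.58 (adjusted p = 0.0416). In the fit of all 12 libraries without the block miR397-3p was at −1.41 (adjusted p = 0.887), a difference of 2 choices at once.

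Lists of families moved in C. sinensis although 0 single miRNAs passed the test. Root development shifted upwards, with 28 of 31 members higher, most between +0.10 and +0.40, and adjusted p = 2.49e-05 (adjusted p = 0.169 with an estimated correlation). Developmental timing shifted upwards with 6 of 6 higher (adjusted p = 0.0118, adjusted p = 0.417 with an estimated correlation), and growth and stress regulators with 13 of 19 higher (adjusted p = 0.0211, adjusted p = 0.444 with an estimated correlation). Conserved land-plant families shifted upwards with 45 of 63 higher (adjusted p = 3.33e-05, adjusted p = 0.169 with an estimated correlation). The other stress families, led by miR477 and csi-miR477b, shifted upwards with 4 of 6 higher (adjusted p = 0.0130, adjusted p = 0.169 with an estimated correlation). Entries with no family name shifted downwards with 24 of 34 lower (adjusted p = 0.0211, adjusted p = 0.169 with an estimated correlation). The lists of auxin signalling (adjusted p = 0.121), nutrient supply (0.461), defence triggers (0.461), small RNA machinery (0.272) and citrus lineage (0.167) did not pass, and in copper and laccase, with 2 members and no test, miR398 and miR397-3p were at −1.58 and −1.41. In each list 0 members passed over all miRNAs and 0 when adjusted over the list alone. None of the 6 list calls held with an estimated correlation, fry called 0, and the count was 3 without 400 µM replicate 1 and 3 without 10 µM replicate 3. The 31 root development members hold 18 sequences and the 63 conserved ones 41. With 1 entry per sequence the growth and stress regulators and the entries with no family name no longer passed.

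Whether the 2 species responded differently was tested as the difference of their boron effects. miR3951 came closest, with a log2 difference of −4.57 (SE 0.93) between the C. grandis and the C. sinensis response (adjusted p = 0.0540), and ci-miRN17 followed at −2.75 (SE 0.68, adjusted p = 0.126). Without C. grandis 10 µM replicate 3 these were −3.26 and −2.08. The 4 miR5206 loci, with identical counts, were at +0.88 (SE 0.31, adjusted p = 0.403). The count was 0 in edgeR with 9 entries at unadjusted p under 0.05, and 2 in DESeq2, miR3951 and ci-miRN17 (adjusted p = 0.00119 for each), with 8 entries at unadjusted p under 0.05. With the replicate block the same 2 miRNAs passed (adjusted p = 0.00938 for each); over all alternatives run the adjusted p of miR3951 ran from 0.00119 to 0.206. The count was 1 without C. grandis 400 µM replicate 2 or 10 µM replicate 1, and 2 without C. grandis 10 µM replicate 2 or 3. The citrus-lineage list, which holds miR3951, shifted downwards in the difference (adjusted p = 0.000117, adjusted p = 0.237 with an estimated correlation, fry adjusted p = 0.355), with 1 of its 3 members, miR3951, passing when adjusted over the list alone and 0 over all miRNAs. The other 10 lists did not pass (lowest adjusted p = 0.192), with 0 members called in either adjustment; root development and auxin signalling had medians of +0.03 and +0.02 and means of −0.05 and −0.08.

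Across the 170 entries, which are not independent replicates, the boron responses of the 2 species were weakly related, with Pearson r = 0.26 (permutation p = 0.002) and Spearman rho = 0.32 (permutation p = 7e-05), computed as 1 relation. Of the 170 entries 108 had the same sign in both species, among them every miR319 locus and both copper-related miRNAs, miR398 and miR397-3p. In C. grandis the sign of miR398 and miR397-3p rests largely on 10 µM replicate 3. For both, 10 µM replicates 1 and 2 lay within the range of the C. grandis libraries at 400 µM. Without the 2 entries farthest from the median in C. grandis r was 0.27, and with 1 entry per sequence r was 0.28 and rho 0.32 (78 of 124 with the same sign). 0 miRNAs were called in both species. At unadjusted p under 0.05, 1 entry, mir7496, was lower in both, where 0.106 would be expected of independent lists. Its C. grandis value (−3.65) rests on 2, 1 and 2 counts at 10 µM against 0 in each library at 400 µM. Among groupings of the libraries within both species, 7 of 100, the real grouping included, gave an r as far from 0, and so did 4 of the 40 that part all 3 same-numbered C. sinensis libraries as the real one does, so that chance was not excluded.

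**Figure D3:**
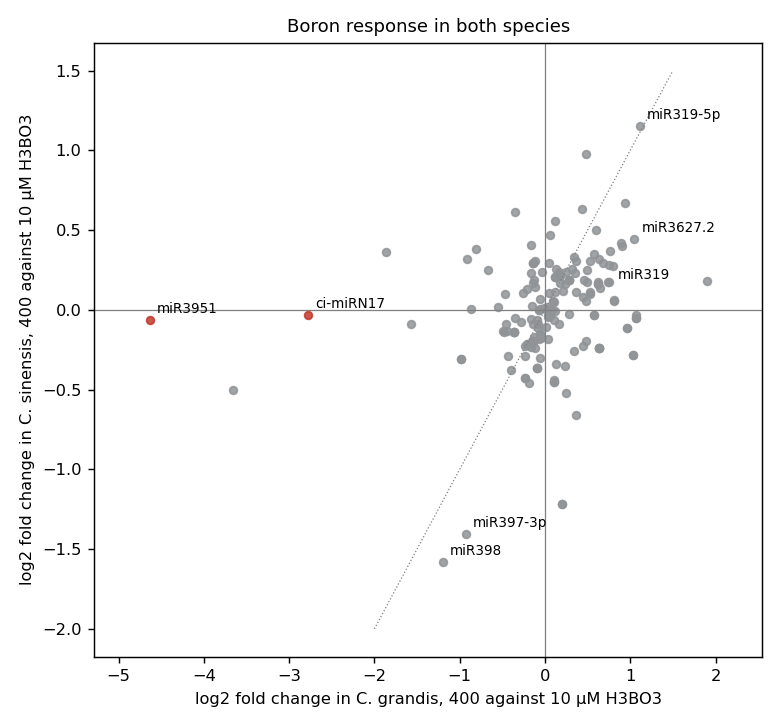
Log2 fold change at 400 against 10 µM H3BO3 in C. grandis (x) and C. sinensis (y) for 170 miRNA loci; red points passed the test in C. grandis and the dotted line marks equal change. miR3951 and ci-miRN17 lie far to the left and near 0 on the y axis, and miR398 and miR397-3p lie below 0 on both axes. The positions of miR398 and miR397-3p on the x axis rest largely on C. grandis 10 µM replicate 3.

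More miRNAs differed between the species than between the boron levels. At 10 µM, 48 of 170 entries (37 sequences) differed, 28 higher and 20 lower in C. grandis, and at 400 µM 49 entries (33 sequences) differed, 35 higher and 14 lower. Of those higher in C. grandis 18 were shared between the levels (5.76 expected of independent lists, Fisher's exact p = 2.18e-08). Of those lower 13 were shared (1.65 expected, Fisher's exact p = 1.05e-13), and 0 changed side. Both tests count loci of 1 sequence as independent, although the 28 and 35 higher entries hold 22 and 22 sequences. The 20 and 14 lower ones hold 15 and 11, so both p-values overstate the evidence. The overlap per sequence was not tested. miR3951 had 124836 ± 20538 CPM in C. sinensis at 10 µM (SD, n = 3) against 1048 ± 1184 CPM in C. grandis, a log2 difference of −6.90 (SE 0.78, adjusted p = 2.07e-05), and −11.47 (SE 0.95, adjusted p = 7.01e-07) at 400 µM. Without C. grandis 10 µM replicate 3 the difference at 10 µM was −8.44 for miR3951 and −8.51 for ci-miRN17, and without C. grandis 400 µM replicate 2 that of miR3951 at 400 µM was −12.23. ci-miRN17 was also lower in C. grandis, at a log2 difference of −7.56 (SE 0.56) at 10 µM and −10.31 (SE 0.64) at 400 µM. mir7496 (scaffold_9_45448) was at −7.55 (SE 0.35) at 10 µM. That value rests on 2, 1 and 2 counts in C. grandis, and its approximate SE understates the counting error of so few. At 400 µM mir7496 was lower by at least 203-fold, where C. grandis had 0 counts (limit of 3 counts over the group). scaffold_8_42593, an unnamed 21-nt sequence at 2 loci, was 585-fold lower in C. grandis at 10 µM (counting interval 104 to 23152) and 231-fold at 400 µM (63.5 to 1910). The 24-nt scaffold_3_10325 was at least 85.8-fold lower at 10 µM and 243-fold at 400 µM (43.3 to 9643). The 585-fold and 243-fold values each rest on 1 C. grandis count. Without C. grandis 10 µM replicate 2 the fitted log2 difference of scaffold_8_42593 moved from −8.69 to −10.51. Without C. grandis 400 µM replicate 2 that of scaffold_3_10325 moved from −7.50 to −9.51.

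In the opposite direction, bra-miR9563a-3p (uuucucuuaucuuuuaucugug, scaffold 1, plus strand, 20985765 to 20986014) was higher in C. grandis by +5.11 (SE 0.42) at 10 µM and +5.36 (SE 0.43) at 400 µM, with adjusted p = 8.92e-07 and 5.76e-07. Without C. grandis 400 µM replicate 1 it was at +4.73 at 400 µM. The unnamed 24-nt scaffold_7_35524 was higher by +4.70 (+4.09 without C. grandis 10 µM replicate 1) and +4.63 (+3.40 without C. grandis 400 µM replicate 3), and bdi-miR7764-5p by +2.55 and +2.93. At 10 µM miR164b-3p, of a family that acts on NAC factors, was higher by +3.90 (SE 0.99) and miR8695 by +2.15 (SE 0.55). miR164b-3p was at +2.01 and lost its call without C. grandis replicate 3 (adjusted p = 0.0844), and lost its call without C. sinensis replicate 2 (0.0558) or 3 (0.0504), and miR8695 without C. sinensis replicate 1 (0.0612) or 3 (0.0568), and over the alternatives other than the replicate block miR164b-3p ran from adjusted p = 0.00117 to 0.0844.

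Among conserved families, miR395, which acts on sulfate uptake and assimilation, was higher in C. grandis at its 3 loci of 1 sequence. It was higher by +1.71 to +1.72 at 10 µM and by +2.83 to +2.84 at 400 µM, and its loci had nearly the same counts, so they are 1 measurement. At 10 µM its calls were lost without C. grandis replicate 1 or 2 or any 1 C. sinensis library (adjusted p = 0.0599 to 0.138). miR390, which starts the trans-acting siRNA pathway of lateral root growth, was lower at both of its loci, which share 1 sequence. It was at −0.76 at 10 µM and −1.10 to −1.11 at 400 µM. At 10 µM it lost its calls without replicate 1 or 2 of either species (0.0943 to 0.153) and under total counts (0.0785 and 0.0793). The 4 miR167 loci (3 sequences) passed in edgeR at 400 µM (+0.65 to +0.77) and 0 of them at 10 µM. However, DESeq2 called 1 of the 4 at 400 µM. All 4 lost their call without C. grandis replicate 2 or any 1 C. sinensis library (0.134 to 0.389). Of the 4, 3 lost it without C. grandis replicate 1 (0.0532 to 0.0969) and 1 without C. grandis replicate 3 (0.0570). Of 7 miR319 loci 2 were lower at 10 µM and 1 at 400 µM (lowest −0.93 and −0.92, at 10 µM −1.57 without C. grandis replicate 3). Of 5 miR171 loci, which hold 2 sequences, 1 and 2 were higher (up to +1.30 and +1.36, the latter +0.75 without C. grandis replicate 3). The miR319 calls were lost at 10 µM without C. grandis replicate 1 or 2 or any 1 C. sinensis library (0.0648 to 0.135), that of gma-miR319g also under total counts (0.0568), and at 400 µM without C. grandis replicate 1 or 3 or C. sinensis replicate 2 (0.0564 to 0.131). The miR171 call at 10 µM was lost without C. grandis replicate 2 or C. sinensis replicate 1 or 2 (0.0695 to 0.0758), and both at 400 µM without C. grandis replicate 3 or any 1 C. sinensis library, 1 also without C. grandis replicate 1 and 1 without C. grandis replicate 2 (0.0591 to 0.252); DESeq2 called 1 of these 2. miR9863 (4 loci of 1 sequence) was higher by +1.42 and +1.20 (at 400 µM not past the threshold without C. grandis replicate 2 or any 1 C. sinensis library, 0.0754 to 0.102) and miR3625 (2 loci) by +1.70 and +1.89, while ptc-miR473a-5p was lower, at −3.20 and −3.57. Over all miRNAs, and when adjusted over the list alone, the members that differed at 10 µM numbered 6 and 2 of 31 in root development, 3 and 3 of 12 in auxin signalling, 3 and 3 of 7 in nutrient supply, 12 and 3 of 63 in the conserved families and 14 and 14 of 34 among entries with no family name. At 400 µM these were 5 and 3, 6 and 6, 3 and 3, 17 and 17, and 8 and 8. Counted the same way at 10 µM, 1 and 0 of 6 differed in developmental timing, 3 and 1 of 19 among growth and stress regulators, 1 and 0 of 8 in the small RNA machinery, 1 and 1 of 3 in the citrus lineage and 1 and 1 of 6 in the other stress families. At 400 µM these were 2 and 4, 4 and 0, 3 and 3, 1 and 1, and 1 and 1, and the defence triggers and the copper and laccase list had 0 at both levels.

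The direction split of the species counts moved with the scaling. Median-of-ratios factors gave 52 entries at 10 µM (23 higher and 29 lower in C. grandis) and 47 at 400 µM (21 and 26), total counts gave 47 (34 and 13) and 48 (31 and 17), and DESeq2 gave 58 (27 and 31) and 49 (21 and 28), of which 47 and 35 were among the entries called in edgeR. The median of all entries moved by −0.14 and −0.18 under median-of-ratios factors and by +0.17 at 10 µM under total counts, so the directions hold relative to that choice. The values of the miRNAs and families named as differing lay farther from 0 than these shifts. Without adjustment 68 and 78 entries had p under 0.05, and 80 (47.1%) and 82 (48.2%) had non-overlapping groups, where chance gives 10%. The replicate block, nested within species, gave 30 and 27 entries, but its species difference is taken at replicate 1 and not as an average over replicates, so it is no check of these calls. Of the 48 and 49 entries 22 and 19 kept their call without each library in turn. The count at 10 µM was 25 without C. grandis replicate 2, 23 without C. sinensis replicate 1 and 27 without C. sinensis replicate 2; that at 400 µM was 31 without C. grandis replicate 3, 21 without C. sinensis replicate 1 and 19 without C. sinensis replicate 2.

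**Figure D4:**
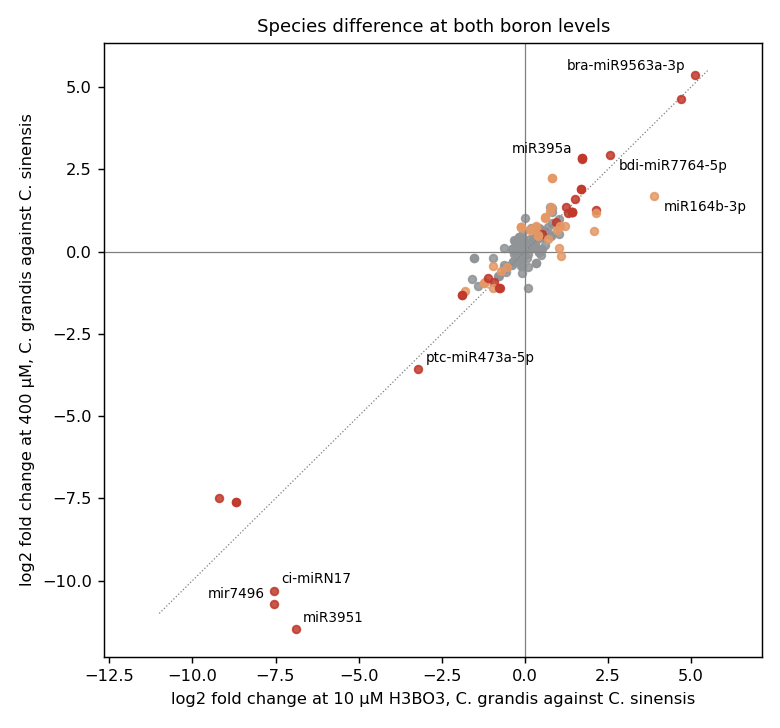
Log2 fold change of C. grandis against C. sinensis at 10 µM (x) and 400 µM H3BO3 (y) for 170 miRNA loci; red points passed the test at both levels, orange at 1 level and grey at neither, and the dotted line marks equal difference. Points below −7 on either axis rest on few or 0 C. grandis counts or on miR3951 and ci-miRN17, so the fitted positions of the scarce ones are not bounds.

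The authors' deposited table of boron-responsive miRNAs held 37 C. grandis entries (23 up, 14 down) and 11 C. sinensis entries (6 up, 5 down). Its column of directions gave the sign of the edgeR fit for 35 of the 35 C. grandis and 10 of the 10 C. sinensis entries that were in the fit, and its log2 fold changes, not readable for mir7496 in C. grandis, differed from the fit by at most 0.06 and 0.02. Of its C. grandis entries 0 had a false discovery rate under 0.05 and 10 had p under 0.05, and the smallest fold was 1.51, while 2 C. sinensis entries, miR398 (−1.60, false discovery rate 0.00545) and scaffold_2_6569 (−1.42, 0.0289), which their C. sinensis table names miR397b-3p and their C. grandis table miR397-3p, had a rate under 0.05. The deposited list of predicted targets gave 39 pairs with 29 distinct genes. miR156 had 7 SBP-domain targets in the C. grandis part, and miR319 had 4 targets including a TCP factor and a Myb-like gene. miR3951 had 1 leucine-rich repeat gene and miR398 had 1 plastocyanin-like gene. The 3 GRAS-domain targets of miR171 are listed for ccl-miR171, which the filter left out and the authors gave as down in C. grandis (−1.50). No target is listed for the tested miR171 loci. miR167h had 1 target, annotated as a Sin-like protein and not as an auxin response factor. Target expression was not analysed here.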

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

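The tests of carry-over, of near-identical entries and of species variants were chosen only after the results were seen, and the species-variant test replaced a first version over all 7 divergent sequences, in which 2 had a near entry of opposite direction; the groupings of libraries were planned, and their division by pairs was not.

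The citrus-lineage list stood out because its boron response differed between the species in the camera test of the difference (adjusted p = 0.000117), with 3 of 3 members lower in C. grandis than in C. sinensis. With an estimated correlation its adjusted p was 0.237. Of its members miR3951 was at −4.57 in the difference (−3.26 without C. grandis 10 µM replicate 3) and both miR3954 loci, which share 1 sequence, were at −0.67.

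The pattern behind it is that miR3951 and ci-miRN17 were lower at 400 µM in C. grandis, where both are scarce, while C. sinensis holds them at high levels. Reads of a near-identical entry are argued against as the source: the nearest entry of each, 2 edits away, was at +0.50 (bra-miR9563a-3p, 95% interval −0.27 to 1.27) and −0.46 (ptc-miR473a-5p, −1.56 to 0.65), wholly above the intervals of −6.24 to −3.03 for miR3951 and −3.95 to −1.62 for ci-miRN17. A candidate explanation that stays open is C. sinensis RNA or reads carried into the C. grandis libraries at 10 µM, where miR3951 stood at 0.376%, 0.329% and 2.02% of its C. sinensis level and ci-miRN17 at 0.420%, 0.246% and 1.07%. The 3 scarcer C. sinensis markers gave 6 counts there (exact Poisson interval 2.20 to 13.1), against 13.97 predicted from the miR3951 share (p = 0.0309) and 8.80 from the ci-miRN17 share (p = 0.496), and 3 counts at 400 µM, which is too few to decide. Of the 6 counts mir7496 gave 5 (7.12 and 4.49 predicted from these shares), scaffold_8_42593 gave 1 (4.62 and 2.91) and scaffold_3_10325 gave 0 (2.24 and 1.41). Carried-over reads would keep the ratio of miR3951 to ci-miRN17 of their source, 4.78 to 6.61 in the 6 C. sinensis libraries. In C. grandis at 400 µM, on 9 to 41 counts of each, the ratio was 1.67 (95% counting interval 0.683 to 4.32), 4.10 (2.02 to 9.18) and 1.83 (1.00 to 3.46) in replicates 1, 2 and 3. There the intervals of replicates 1 and 3 lie below the C. sinensis range. In C. grandis at 10 µM the ratio was 4.97 (95% counting interval 3.79 to 6.61), 7.42 (5.43 to 10.4) and 10.5 (8.99 to 12.2) in replicates 1, 2 and 3. This argues against carry-over with the ratio of these libraries as the whole source in replicate 3. The intervals of replicates 1 and 2 overlap the C. sinensis range, so carry-over stays open for these 2 and as a part of replicate 3. A response of C. grandis to boron, which the design names, stays open as well, and for replicates 1 and 2 neither can be told apart from the other on these counts.

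Between the species miR3951 and bra-miR9563a-3p, which lie on the same scaffold, differ in opposite directions. That a species variant only moves reads of 1 locus from one entry to the other is argued against as the whole cause, since the summed counts still differed, by −1.98 (95% interval −2.65 to −1.31) at 10 µM and −1.81 (−2.47 to −1.14) at 400 µM. The other 5 sequences over 16 times apart between the species at both levels are those with 0 entries within 4 edits that differed the other way. That 0 was fixed by how they were set apart, so it tests nothing about a variant. scaffold_3_10325, scaffold_8_42593, mir7496 and scaffold_7_35524 had 0 other tested sequences of any direction within 4 edits. The nearest of ci-miRN17, ptc-miR473a-5p, differed in the same direction (−3.20 at 10 µM and −3.57 at 400 µM). A variant whose reads were not counted anywhere, and a difference in expression between the species, both stay open and were not tested.

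For comparisons of 3 against 3 libraries the 10 possible groupings are too few for a share under 0.05. In C. grandis 2 of 10 groupings, the real included, gave as many boron calls (real 2, highest other 3), and in C. sinensis 10 of 10 did (real 0, highest other 0), which a real count of 0 fixes in advance and which says nothing. For the species at 10 and at 400 µM 1 of 10 did in each case, the real grouping itself (48 and 49, highest other 0). For the lists 1 of 10 did in each species (C. grandis real 5, highest other 4; C. sinensis real 6, highest other 5). For the difference of the boron effects the real count of 0 fixes the outcome as well (100 of 100 drawn groupings, highest other 4), so nothing follows from it. For the relation of both responses 7 of 100 gave an r as far from 0 as 0.26 (highest other 0.428), so that chance is not excluded. Since the C. sinensis libraries pair by number, the groupings were also divided by pairs. Of the 40 that part all 3 C. sinensis pairs, as the real one does, 4 gave such an r (highest other 0.428), and of the 60 that part 1 pair 3 did (highest 0.367). For the C. sinensis lists 1 of the 4 groupings that part all 3 pairs, the real one, gave 6 lists (highest other 5), and of the 6 that part 1 pair 0 did (highest 3).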

How the results depend on the processing

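All alternatives were planned except 5 that were chosen after seeing the data: 1 entry per sequence, only entries of 20 to 22 nt, the replicate block in C. sinensis only, the replicate block in a fit of 1 species, and lists without miR3951 and ci-miRN17. Of the counts and the relation, 93 alternative values stayed within 1.5 times the reported value, or within its spread, and 44 moved; of the values for single named miRNAs 929 kept direction and side of the threshold, 28 newly passed it, 10 no longer passed it and 19 changed sign. The species comparisons with the replicate block are left out of these numbers, because the block is nested within species and the difference is then taken at replicate 1, which checks neither the counts nor the calls. The count of boron-changed miRNAs in C. grandis, 2, was 4 under median-of-ratios scaling, 4 under total counts, 5 in DESeq2, 0 with only the 6 libraries of the species, 1 with these and the replicate block, 1 with entries of 20 to 22 nt and 0 to 8 without 1 library. That in C. sinensis, 0, was 1 with its 6 libraries and the replicate block. The count of differing boron responses, 0, was 1 under median-of-ratios scaling, with a mean CPM of at least 10, with identical loci merged and with 1 entry per sequence, 2 under total counts, in DESeq2, without a filter and with the replicate block, and 0 to 2 without 1 library. The species count at 10 µM, 48, was 30 with the replicate block, 20 with entries of 20 to 22 nt and 23 to 43 without 1 library. That at 400 µM, 49, was 27 with the block, 28 with identical loci merged, 28 with 1 entry per sequence, 17 with entries of 20 to 22 nt and 19 to 62 without 1 library; merging loci and limiting lengths leave fewer entries to count. Lists in C. grandis, 5, numbered 3 with identical loci merged, 2 with 1 entry per sequence, 0 with an estimated correlation, 1 in fry, 3 without miR3951 and ci-miRN17 and 1 to 6 without 1 library. Lists in C. sinensis, 6, numbered 0 with an estimated correlation, 0 in fry and 3 to 7 without 1 library. With 1 entry per sequence its lists of growth and stress regulators and of entries with no family name no longer passed. The relation of both responses was r = 0.18 to 0.39 without 1 library. Among the miRNAs chosen by the naming rule, sign changes were seen only in miR319 and miR171 loci that had not passed. The C. grandis values of miR398 and miR397-3p were not followed through the alternatives. In C. grandis ath-miR171b-3p (+0.13) was at −0.14 under total counts, −0.14 without a filter and −0.14 with a mean CPM of at least 10. It was at −0.15 with entries of 20 to 22 nt and at −0.29 to 0.16 without 1 library. Without 1 library, 3 ath-miR319a loci in C. grandis ran from −0.071 to 0.58 (scaffold_2_8704), −0.14 to 0.58 (scaffold_3_9221) and −0.026 to 0.51 (scaffold_5_23391) and gma-miR319g from −0.066 to 0.51, and in C. sinensis miR171b.2 and miR171b.3 each from −0.15 to 0.35. Where not stated, the cause was not tested. Depth limits scarce sequences, since 3 counts correspond to 2.82 to 4.59 CPM in the C. grandis libraries and 3.17 to 6.26 CPM in the C. sinensis libraries.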

Other observations

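The average-effect test was chosen only after the results were seen, and so were the groupings of libraries by which the length classes were judged; the tests of the length classes themselves were chosen before.

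The shares of the length classes are given as values, with no test between the species. In C. grandis 22-nt entries held 20.1% of counts at 10 µM and 21.5% at 400 µM (SD 4.69 and 5.99, n = 3), and in C. sinensis 9.62% and 10.3% (SD 0.711 and 0.901). bra-miR9563a-3p, a 22-nt sequence, averaged 29515 CPM in C. grandis and 856 CPM in C. sinensis at 10 µM.

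A hypothesis from the values above is that miR398, a copper-related miRNA, may be lower at 400 µM on average over both species. Its C. grandis value rests largely on 10 µM replicate 3, at 775.0 CPM. The C. grandis 10 µM replicates 1 and 2, at 155.9 and 163.95 CPM, lay within the 400 µM range of 135.6 to 172.5 CPM. In a test of the average boron effect miR398 had adjusted p = 0.146, which neither shows nor excludes it; the bound set for that test, an adjusted p of 0.05 or more, was a poor one, since a missed threshold excludes nothing. miR3951 was the only miRNA that passed (−2.35, adjusted p = 0.0430), with 24 entries at unadjusted p under 0.05, and its average rests on C. grandis, since in C. sinensis it was at −0.07.

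A further hypothesis was that 24-nt miRNAs may respond to boron unlike those of 20 to 22 nt. Over 49 sequences of 24 nt and 70 of 20 to 22 nt, the mean log2 fold change of the 24-nt class was lower by a difference of −0.26 in C. grandis (permutation p = 0.0814, adjusted p = 0.0814) and −0.17 in C. sinensis (permutation p = 0.0125, adjusted p = 0.025). Among the 10 groupings of the libraries, 5 in C. grandis and 4 in C. sinensis gave a difference as large (highest other 0.601 and 0.237). Each of the other groupings mixes the boron levels 2 to 1. Although the C. sinensis libraries pair by number, these groupings were not divided by pairs. The permutation treats sequences as independent, which was not tested, and the 10 groupings are too few for a share under 0.05. The bound set in advance, a p of 0.05 or more, was met in C. grandis but was a poor bound, since a missed threshold excludes nothing, and a response of the length class stays open in both species.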
